A study of Mus musculus with 5 samples.

How the data were processed

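Messenger RNA was measured by sequencing in 5 libraries from mouse retinal cells, 2 labelled as given a GFP plasmid and 3 labelled as given a Zfp292 plasmid. In those 3 the reads counted under Zfp292 were not detectably higher. Per the labels' protocols, plasmids with the CAG promoter were electroporated at postnatal day 0 and tissue was taken 4 days later. Sorted GFP-positive cells gave RNA by a column kit, and libraries were made from 1.3 µg of total RNA with a SMARTER messenger RNA kit. The genome builds named are GRCm38 and mm10, per the submitters' processing notes. The aligner, the counter, the gene annotation and the method of scaling are not given in the sources used here, nor is whether counting used strand.

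The deposited file is a table of 24594 genes by 5 libraries, with Entrez identifiers and symbols and 0 columns of other samples. The deposited values are a normalised signal per gene: read counts divided by 1 factor per library, as the values themselves show. In each library every value was a whole multiple of the smallest value above 0, within a tolerance of 1e-06 of a read, for 100% of values. A read was worth 1.09 and 0.770 in the control libraries and 1.14, 0.940 and 1.05 in libraries 1, 2 and 3 labelled Zfp292-OE. Whole reads were recovered from these steps, and at this depth 15373 to 16275 genes had at least 10 reads in a library. Some abundant genes with many near-identical copies in the genome had low values (Gapdh 1617 in control library 1), so genes of such families are uncertain. The 13 mitochondrially encoded genes and Hbb-bs, Hba-a2 and Ahsp were not matched in the table and were not analysed here. The 18 genes without a symbol were kept under their Entrez identifiers. Coordinates come from the RefSeq annotation of GRCm38.p6, in which 24570 identifiers matched, and span the whole gene.

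Libraries were grouped by their labels. Genes with a mean value of at least 10 over the 5 libraries were tested with limma 3.58.1 (R 4.3.3, trend) on log2(value + 1), libraries labelled Zfp292-OE minus control, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are differences of mean logs, so for genes near 0 in a library they can lie far from the ratio of the means, in either direction. Rxfp2, for example, has a log2 fold change of 5.19, and 3.46 in edgeR. It is 2.46 without control library 1 and 7.92 without control library 2. For 29 gene lists of cell types, cell cycle, pathways and stress, fixed before the data were examined, list tests used camera on the same fit with a preset correlation of 0.01, adjusted over the 26 lists with at least 5 tested genes, and camera with an estimated correlation and fry were run beside it. The sex-linked list was read per library only. Lists share some genes. Counts adjusted over the list alone use the p-values of its members only. Because the values were normalised, limma and not a count model gave the main result, as planned. edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the whole reads were alternatives.

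The named genes followed a rule also fixed before the data were examined: Zfp292; the 10 genes with the largest change in each direction among those past the threshold with a mean of at least 50, no overlap between groups and a proper gene symbol; the 4 members of each list past the threshold, and 2 of each other list, with the smallest p. Some genes this rule takes are not reported here. A few further genes, named in the closing observations, were chosen after their values were seen. Where a group had 0 reads, the fold is given against 3 reads over the group as a lower bound. For 1 to 3 reads the ratio has an exact binomial 95% interval. Both cover counting error only, since reads without molecular identifiers are not independent molecules.

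The scripts were tested on simulated data, with counts drawn for the 16316 tested genes from the means, spread and depths of these libraries and 200 genes changed, in 10 datasets. In these datasets limma recovered 4.48% of genes changed 1.5-fold, 28.4% of those changed 2-fold and 67.3% of those changed 4-fold. Of its calls, 12.4% were not changed genes. An adjusted threshold depends on how many genes change, and 2836 were called in the real data, so these shares need not hold there. Camera, at an unadjusted p below 0.05, called a changed list of 15 genes in 10 of 10 datasets and an unchanged list in 1. The simulated genes were drawn independently, so this does not test false calls for lists whose genes move together.

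Alternatives were pseudocounts of 0.5 and 10, no filter, a filter at a mean of 50, TMM scaling, quantile normalization, equal totals, array weights, edgeR, DESeq2, a replicate block and leaving out each library in turn. Leaving out libraries 1 and 3 labelled Zfp292-OE together was added after the data were seen. For the closing tests, trends of fold change with GC content and transcript length were removed by loess (span 0.3). Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.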

Results

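RNA sequencing was done on cells from the developing mouse retina that had been given a plasmid in the living animal. Zfp292 is a large zinc finger protein of the nucleus. Per the labels, a plasmid carrying Zfp292, or one carrying green fluorescent protein (GFP) as the control, was electroporated into the eyes of newborn pups under the CAG promoter, which drives strong expression in most cell types. Retinas were taken 4 days later and dissociated, and GFP-positive cells, which the labels call RPC, were collected by fluorescence-activated sorting. The labels give 2 control libraries and 3 libraries labelled Zfp292-OE, and the comparison asks how gene expression in these cells differed between the groups. Reads assigned to genes numbered 103096224 and 137683716 in control libraries 1 and 2. In libraries 1, 2 and 3 labelled Zfp292-OE they numbered 114197740, 135442444 and 117441152. Nothing in the labels says whether the libraries of a group came from separate animals or litters, so p-values measure only the spread between these samples, which may be technical.

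Cell cycle genes were higher in the libraries labelled Zfp292-OE, with all 36 tested members of the G1/S and G2/M lists raised, while genes of rods and bipolar cells were lower. Some genes of Müller glia (7 of 15), astrocytes (4 of 7), cones (4 of 12) and maturing neurons (6 of 15) fell as well. None of the list calls held in camera with an estimated correlation (adjusted p = 0.12 or above, 0.43 for these 4 lists), a test with little power at 5 libraries. The preset correlation of 0.01 behind those calls lay under the estimate for every such list but bipolar cells. A few progenitor regulators rose, among them Hes1, Hes5 and Ccnd1. Zfp292 itself did not differ detectably between the groups, so each direction given here is that of the labels and not of a measured rise in Zfp292.

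Zfp292 (Entrez 30046, GRCm38 chromosome 4, 34803110 to 34882983) had normalised read counts of 13288 and 14756 in the control libraries. The libraries labelled Zfp292-OE had 14631, 13197 and 15534. The means were 14022 ± 1038 (SD, n = 2) and 14454 ± 1179 (SD, n = 3). The log2 fold change was 0.04 (SE 0.14), a fold of 1.03 with an upper 95% limit of 1.29, and limma gave an adjusted p of 0.87 (edgeR 0.96, range over 17 alternatives 0.39 to 0.98). The labels do not state the sequence or species of the insert, and the table has 0 rows named for GFP, so the plasmids themselves could not be read from these values.

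Of 16316 genes tested with limma at an adjusted p below 0.05, 2836 differed between the groups, 1632 higher and 1204 lower in the libraries labelled Zfp292-OE. Reads counted under Zfp292 were not detectably higher in those libraries. Among them 1399 changed at least 2-fold, and 241 rose and 208 fell at least 4-fold. The groups did not overlap for any of the 2836 genes. Non-overlap held for 49.9% of all tested genes, against 20% that chance gives for 2 libraries against 3. The edgeR quasi-likelihood test on the recovered whole reads called 2621 genes, 1351 higher and 1270 lower, and 2501 of the limma calls were shared with it in the same direction. Scaling all libraries to equal totals gave 913 higher and 1986 lower genes and moved the median log2 fold change of all tested genes from −0.06 to −0.27. The count rested on having both controls: without control library 1, or without control library 2, limma called 1 gene, although 4390 and 3534 genes, against 5351 with all libraries, had an unadjusted p below 0.05. Without library 1 labelled Zfp292-OE the count was 1657.

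**Figure D1:**
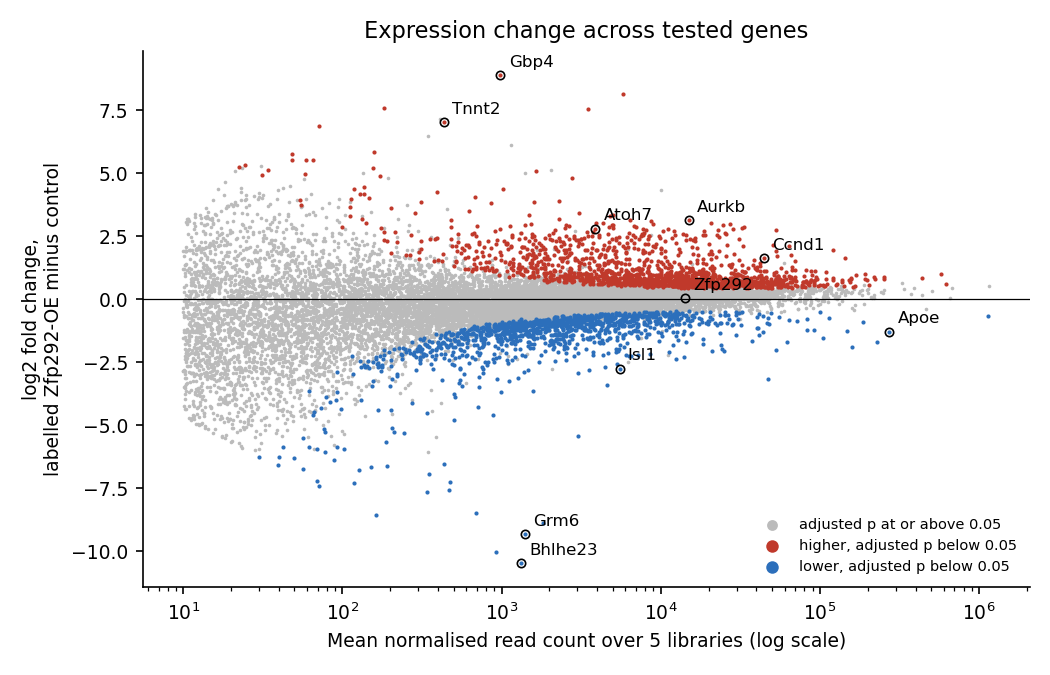
Log2 fold change, libraries labelled Zfp292-OE minus control (y axis), against the mean normalised read count over 5 libraries on a log scale (x axis) for the 16316 tested genes, with 1632 higher in red and 1204 lower in blue at a limma adjusted p below 0.05. Zfp292 lies at 0.04, Aurkb at 3.12 and Isl1 at −2.75.

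Genes of DNA replication and of mitosis rose together in all 3 libraries labelled Zfp292-OE. All 18 tested genes of the G2/M list rose, 18 also when adjusted over the list alone, with a median log2 fold change of 2.71. Aurkb, a kinase of the chromosomal passenger complex (chromosome 11, 69045624 to 69051664), rose 8.71-fold, from 2561 ± 381 (SD, n = 2) to 23328 ± 8598 (SD, n = 3), with a log2 fold change of 3.12 (SE 0.28) and an adjusted p of 0.00032 in limma. The mitotic cyclin Ccnb2 rose by 2.96 on the log2 scale, the spindle assembly factor Tpx2 by 2.78 and the kinetochore motor Cenpe by 2.49. All 18 tested genes of the G1/S list rose, 18 also when adjusted over the list alone, with a median of 1.93. Mcm6, a subunit of the replicative helicase (chromosome 1, 128331575 to 128359705), went from 4300 ± 272 (SD, n = 2) to 22682 ± 6042 (SD, n = 3). The replication licensing factor Cdc6 rose by 2.93, the helicase subunit Mcm3 by 2.21 and the chromatin assembly subunit Chaf1b by 1.95. In camera with a preset correlation the adjusted p was 1.2e-20 for G2/M and 2.7e-18 for G1/S. Neither call held with an estimated correlation, at an adjusted p of 0.43 for both lists, the highest over 19 alternatives (lowest 9.3e-46 and 2.1e-32). Relative to the control mean, the mean of the G2/M list was 2.72, 3.05 and 2.01 in libraries 1, 2 and 3 labelled Zfp292-OE.

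Inhibitors of the cell cycle moved in both directions. Of 13 tested, 3 rose, 2 fell and 8 did not pass, and 4 rose and 2 fell when adjusted over the list alone. The pocket protein Rbl1 rose by 2.02 on the log2 scale and the imprinted Cdk inhibitor Cdkn1c fell by 0.85. The list did not pass in camera (adjusted p = 0.46), and its median of −0.05 differed in sign from its mean of 0.15 and from the upward direction of the test.

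Progenitor genes split between those that rose and those that did not. Of 17 tested, 6 rose, 1 fell and 10 did not pass, with the same counts of 6 and 1 when adjusted over the list alone. The Notch effector Hes1 (chromosome 16, 30065357 to 30067796) rose from 16709 ± 2004 (SD, n = 2) to 37614 ± 1125 (SD, n = 3), a log2 fold change of 1.18 (SE 0.14) with an adjusted p of 0.00072. The Notch effector Hes5 rose by 1.17, and the G1 cyclin Ccnd1 rose 3.11-fold. The progenitor list passed in camera (adjusted p = 0.0019, median 0.29), but not with an estimated correlation (adjusted p = 0.43). Its median was 0.54 without control library 2. It also missed the threshold without control library 1 (adjusted p = 0.099) and after quantile normalization (adjusted p = 0.090), with a range of 0.00010 to 0.43 over 19 alternatives.

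Of 12 genes of the Notch list, 3 rose, 0 fell and 9 did not pass, again 3 when adjusted over the list alone. Those that rose were Hes1, Hes5 and Id1 (log2 fold change 0.92), an inhibitor of basic helix-loop-helix factors, and Heyl had a value of 0.61 (adjusted p = 0.10, 0.046 in DESeq2, range over 17 alternatives 0.046 to 0.63). The list passed narrowly in camera (adjusted p = 0.026, median 0.22), not with an estimated correlation (adjusted p = 0.43), after quantile normalization (0.051), without control library 1 (0.27) or without library 1 labelled Zfp292-OE (0.063). The range over 19 alternatives was 0.0043 to 0.43, and the median was 0.41 without control library 2. Of 10 hedgehog genes 3 rose, 0 fell and 7 did not pass, with 4 higher when adjusted over the list alone. Hes1 and Ccnd1, which also stand in the progenitor list, were 2 of the 3, and the other was the transcription factor Gli3 (0.97), which lost its call without library 1 labelled Zfp292-OE (adjusted p = 0.060, range over 17 alternatives 0.00064 to 0.20). Hhip, a target and inhibitor of the pathway, had a log2 fold change of 0.93 (adjusted p = 0.071, range over 17 alternatives 0.021 to 0.25). It passed after quantile normalization (0.037), in DESeq2 (0.021), with a replicate block (0.045) and without library 3 labelled Zfp292-OE (0.042). The hedgehog list passed in camera (adjusted p = 0.0047, median 0.95), but not with an estimated correlation (adjusted p = 0.43) or without control library 1 (adjusted p = 0.12, median 0.60), with a range of 0.00047 to 0.43 over 19 alternatives.

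Atoh7, the factor required for retinal ganglion cells (chromosome 10, 63099785 to 63101280), was 6.97-fold higher, at 812 ± 75 (SD, n = 2) in control and 5947 ± 2400 (SD, n = 3) in the libraries labelled Zfp292-OE (adjusted p = 0.00052). It stands in the neurogenic list, of which 4 of 16 rose, 2 fell and 10 did not pass, the same when adjusted over the list alone. The neuropeptide precursor Penk rose by 1.62. The neurogenic list did not pass in camera (adjusted p = 0.093, median 0.32), but did without library 1 labelled Zfp292-OE (adjusted p = 0.0050, range over 19 alternatives 0.0050 to 0.58). Its median was 0.50 in that fit and 0.13 without library 3. Of 12 genes of early progenitors, 3 rose, 0 fell and 9 did not pass, 3 when adjusted over the list alone, among them Atoh7 and the growth factor Fgf15 (1.54). The early list had a median of 0.04 and a camera adjusted p of 0.17, and passed after quantile normalization (adjusted p = 0.048, range over 19 alternatives 0.048 to 0.43). Of 12 genes of late progenitors, 2 rose, 2 fell and 8 did not pass, the same when adjusted over the list alone. Hes5 rose and the retinoid-binding Rlbp1 fell by 0.86, and the late list had a median of −0.12 and a camera adjusted p of 0.75.

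Rod genes were lower in all 3 libraries labelled Zfp292-OE, by a similar amount. Of 19 tested, 0 rose, 17 fell and 2 did not pass, 17 also when adjusted over the list alone, with a median log2 fold change of −1.89. The phosphodiesterase subunit Pde6b (chromosome 5, 108388373 to 108431743) went from 24050 ± 4245 (SD, n = 2) to 4665 ± 327 (SD, n = 3), with a log2 fold change of −2.36 (SE 0.16) and a limma adjusted p of 0.00025. The outer segment proteins Rp1 (−2.06) and Rom1 (−1.67) fell as well. The camera adjusted p was 1.8e-16, and it was 0.12 with an estimated correlation (range over 19 alternatives 7.3e-38 to 0.12). Relative to the control mean, the mean of the rod list was −1.68, −1.61 and −1.87 in libraries 1, 2 and 3.

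Of 12 cone genes 0 rose, 4 fell and 8 did not pass, with 4 lower when adjusted over the list alone. The cone transducin subunit Gnb3 (−1.13) and the cone arrestin Arr3 (−2.80, and −2.02 without library 3 labelled Zfp292-OE) fell. The phosphodiesterase subunit Pde6c (−1.94) and the opsin Opn1mw (−5.30) were close to the threshold, with adjusted p = 0.044 for both, and each lost its call without library 1 labelled Zfp292-OE (0.091 and 0.064). Over 17 alternatives their adjusted p ranged from 0.0099 to 0.29 and from 0.011 to 0.33, and the value of Opn1mw was −3.49 without library 3 and −6.46 without library 2. The cone list passed in camera (adjusted p = 0.0047, median −0.67), but not with an estimated correlation (adjusted p = 0.43) or without control library 1 (adjusted p = 0.057), with a range of 0.00074 to 0.43 over 19 alternatives. The cone median was −0.41 without library 3 labelled Zfp292-OE. The mean of the cone list relative to control was −0.88, −0.80 and −2.21 in libraries 1, 2 and 3.

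Most bipolar genes fell. Of 14 tested, 0 rose, 10 fell and 4 did not pass, 10 when adjusted over the list alone, with a median of −1.73. Isl1, a LIM-homeobox factor of bipolar, amacrine and ganglion cells (chromosome 13, 116298270 to 116309688), fell from 11210 ± 1195 (SD, n = 2) to 1718 ± 524 (SD, n = 3), with an adjusted p of 0.00041. Bhlhe23, a factor of rod bipolar cells, had 7126 reads over the control libraries and 6 over the others. Grm6, the glutamate receptor of ON bipolar cells, had 7871 and 34, and the kainate receptor subunit Grik1 fell by 4.60 on the log2 scale. In camera the adjusted p was 1.2e-07, and it was 0.12 with an estimated correlation (range over 19 alternatives 1.5e-13 to 0.12).

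Few markers of amacrine, horizontal and ganglion cells passed the test, and their levels varied between libraries. The mean of amacrine and horizontal genes relative to control was −0.99, 0.19 and −0.16 in libraries 1, 2 and 3, and that of ganglion cell genes was 0.24, −0.58 and 0.53. Of 16 amacrine and horizontal genes, 1 rose, 2 fell and 13 did not pass, the same when adjusted over the list alone, and the camera adjusted p was 0.17 (median −0.28). The homeobox gene Prox1 (−0.88) and the GABA-synthesising enzyme Gad1 (−1.48) fell. Of 15 ganglion cell genes, 0 rose, 2 fell and 13 did not pass, the same when adjusted over the list alone, and the camera adjusted p was 0.92. The factors Ebf3 and Ebf1, which amacrine cells also express, fell (−0.98 and −1.07). Ebf1 lost its call in each fit that left out a library, and Ebf3 without library 1 labelled Zfp292-OE (adjusted p = 0.062 and 0.050 in that fit, ranges over 17 alternatives 0.0033 to 0.21 and 0.00022 to 0.22). The ganglion median of −0.09 and the downward direction of the test differed in sign from the mean of 0.06. Of 15 genes of neuron maturation, 0 rose, 6 fell and 9 did not pass, with 7 lower when adjusted over the list alone. The synaptic vesicle proteins Syt1 (−1.36) and Syp (−1.33), the splicing regulator Celf4 (−0.94) and the SNARE protein Snap25 (−0.79) fell. Snap25 lost its call without library 1 labelled Zfp292-OE (adjusted p = 0.053, range over 17 alternatives 0.00034 to 0.29). The maturation list passed in camera (adjusted p = 0.00040, median −0.59), but not with an estimated correlation (adjusted p = 0.43, range over 19 alternatives 5.1e-06 to 0.43).

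Some glial genes fell in the libraries labelled Zfp292-OE. Of 15 Müller glia genes, 1 rose, 7 fell and 7 did not pass, with 2 and 7 when adjusted over the list alone. The lipid carrier Apoe (chromosome 7, 19696244 to 19701310) fell from 423518 ± 79043 (SD, n = 2) to 173474 ± 25840 (SD, n = 3). The extracellular chaperone Clu (−1.49), Rlbp1 (−0.86) and the receptor Gpr37 (−0.80) fell too. The list passed in camera (adjusted p = 0.0057, median −0.69), but not with an estimated correlation (adjusted p = 0.43) by fry (0.12) or without control library 2 (adjusted p = 0.15), with a range of 8.6e-05 to 0.43 over 19 alternatives. Of 7 astrocyte genes, 0 rose, 4 fell and 3 did not pass, with 6 lower when adjusted over the list alone. The glycolytic enzyme Aldoc (−1.81) and the glutamate transporter Slc1a2 (−0.91) fell, both also expressed in other cells of the retina. The folate enzyme Aldh1l1 (−3.86, 33 reads over the labelled libraries) and the calcium-binding S100b (−2.17) fell as well, though each lost its call in at least 1 fit that left out a library (Aldh1l1 0.053 without library 1, S100b 0.060 without library 3). Over 17 alternatives their adjusted p ranged from 0.00026 to 0.19 and from 0.0031 to 0.30. For astrocytes the camera adjusted p was 0.0040 (median −1.81), and it was 0.43 with an estimated correlation and 0.075 by fry (range over 19 alternatives 0.00021 to 0.43).

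Markers of cells from outside the neural retina also differed between libraries. None of 15 microglial genes passed in limma (0 higher and 0 lower, also 0 when adjusted over the list alone), and edgeR called 0, while 2 had an unadjusted p below 0.05. The median log2 fold change was −2.13 (−3.29 without library 2 labelled Zfp292-OE, −0.75 without library 3, −1.05 without control library 2), and Laptm5 and Csf1r had values of −2.51 (adjusted p = 0.11) and −4.44 (adjusted p = 0.13). Without library 2 labelled Zfp292-OE they were −3.54 and −6.04 and passed (adjusted p = 0.014 and 0.034, ranges over 17 alternatives 0.014 to 0.67 and 0.034 to 0.56), and without library 3 they were −1.58 and −2.01. The list passed in camera (adjusted p = 0.019), not with an estimated correlation (adjusted p = 0.59), without control library 2 (0.46) or without library 3 labelled Zfp292-OE (0.13). The range over 19 alternatives was 0.00012 to 0.80. Its mean relative to control was −1.39, −0.21 and −4.18 in libraries 1, 2 and 3, and the controls themselves lay at −0.81 and 0.81. Of 12 vascular genes, 1 rose, 3 fell and 8 did not pass, with 1 and 6 when adjusted over the list alone. The 3 that fell all stand in the pericyte group of the closing observations as well. The tight junction gene Cldn5 rose 10.2-fold, from 219 ± 22 (SD, n = 2) to 2317 ± 800 (SD, n = 3), and the pericyte gene Rgs5 fell by 7.65 (−6.70 without library 1 labelled Zfp292-OE, −8.75 without library 2), with 1729 reads over the control libraries and 19 over the others. The camera adjusted p was 0.056 (median −0.82), and 0.029 without library 1 labelled Zfp292-OE (range over 19 alternatives 0.023 to 0.43). Of 7 pigment epithelium genes 0 passed in limma (0 in edgeR, 0 at an unadjusted p below 0.05), with a median of 1.40 and a camera adjusted p of 0.14 (0.046 after quantile normalization, range over 19 alternatives 0.023 to 0.50). That median was 0.55 without control library 1, and 0.86 and 0.58 without library 1 or 2 labelled Zfp292-OE. Pmel had a log2 fold change of 3.35 (adjusted p = 0.22), but 0.097 without control library 1 and 6.61 without control library 2. Of 7 lens crystallin genes, 0 rose, 2 fell and 5 did not pass, 2 when adjusted over the list alone, and the camera adjusted p was 0.13 (median −0.56). The lens median was −0.24 without control library 2, and −1.36, −1.35 and −1.37 without control library 1 or without library 1 or 2 labelled Zfp292-OE. The small heat shock protein Cryab (−2.21, and −1.37 without library 2) did not pass in edgeR (adjusted p = 0.062, range over 17 alternatives 0.00018 to 0.39), and the lens protein Cryba1 (−1.63) lost its call without library 3 labelled Zfp292-OE (adjusted p = 0.079, range 0.020 to 0.31). The 3 tested erythroid genes were too few for a list test, and 0 of them passed in limma or edgeR, nor did any have an unadjusted p below 0.05. With a replicate block Hba-a1 passed in limma (adjusted p = 0.038).

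**Figure D2:**
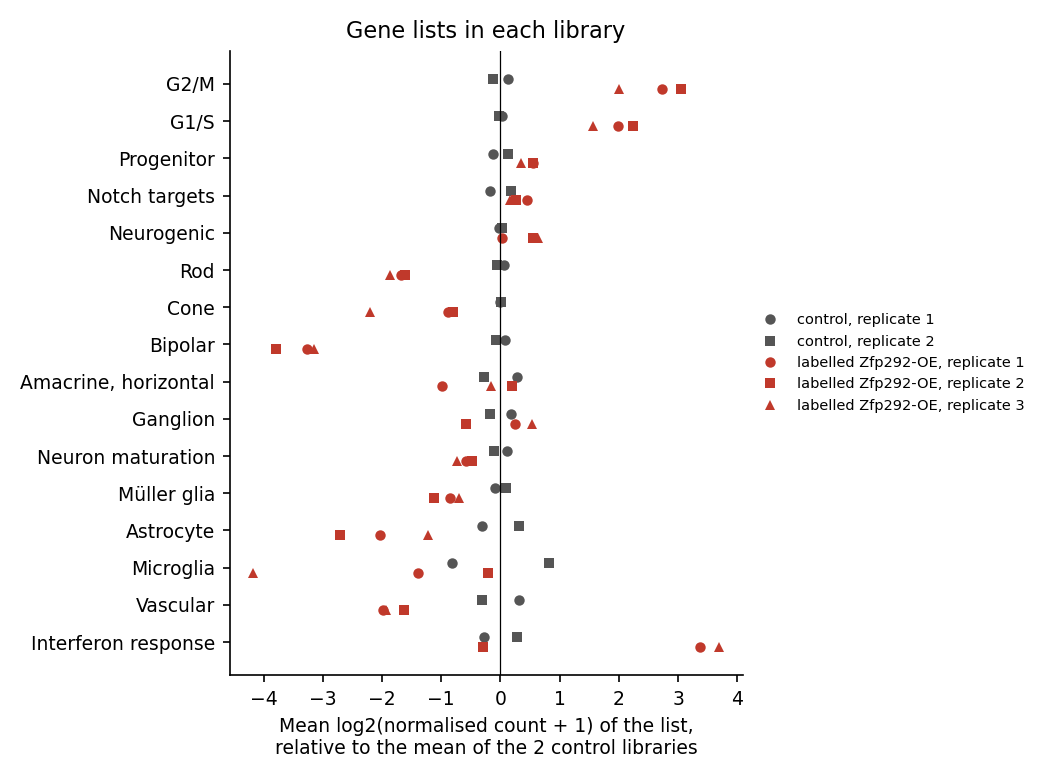
Mean log2(normalised count + 1) of each gene list in each library relative to the mean of the 2 controls, with controls in grey, libraries labelled Zfp292-OE in red and the replicate number shown by shape. In the 3 labelled libraries the G2/M list lies at 2.01 to 3.05 and the rod list at −1.87 to −1.61, while the interferon list lies at 3.36 and 3.70 in 2 of them and at −0.30 in the other.

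A few genes of the interferon response rose, and the level of the list differed between the libraries labelled Zfp292-OE. Its mean relative to control was 3.36, −0.30 and 3.70 in libraries 1, 2 and 3, a difference that was not tested. Of 19 tested, 4 rose, 1 fell and 14 did not pass, 4 and 1 also when adjusted over the list alone. Usp18, a brake on interferon signalling, rose by 2.07, with normalised counts of 653 and 683 in the controls and 3121, 1431 and 4987 in libraries 1, 2 and 3. Rtp4, an interferon-induced chaperone, had normalised counts of 68 and 243 in the controls and 2606, 322 and 8212 in the others, and lost its call without library 1 or 3 (adjusted p = 0.11 and 0.077, range over 17 alternatives 0.00047 to 0.48). The log2 fold change of Rtp4 was 3.88, 2.83 without library 3 and 5.16 without library 2. Ifit2 (1.23) and the interferon signal transducer Stat2, which was lower (−1.07), lost their calls in each fit that left out a library (adjusted p = 0.073 and 0.095 without library 1, ranges over 17 alternatives 0.012 to 0.27 and 0.0040 to 0.25). The list passed in camera (adjusted p = 0.0030, median 2.07), but not with an estimated correlation (adjusted p = 0.50) or without control library 1 (adjusted p = 0.066). The interferon median was 1.23 without library 3. With libraries 1 and 3 both left out, a choice made after the data were seen, its median was −0.22 (adjusted p = 0.85), and over 19 alternatives the adjusted p ranged from 7.4e-11 to 0.85.

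Stress lists did not pass. Of 15 p53 target genes, 2 rose, 0 fell and 13 did not pass, with 3 and 1 when adjusted over the list alone. The Cdk inhibitor Cdkn1a rose by 1.14, and the receptor Eda2r (4.17) did not pass in edgeR (adjusted p = 0.083, range over 17 alternatives 0.0053 to 0.27). The value of Eda2r was 5.93 without control library 1 and 2.41 without control library 2. The p53 list had a camera adjusted p of 0.86, and its median of −0.03 differed in sign from its mean of 0.24 and the upward direction of the test. Of 13 immediate early genes, 0 rose, 2 fell and 11 did not pass, 2 when adjusted over the list alone. Ier3 fell by 1.21, and the zinc finger factor Egr1 (−0.85) lost its call without library 1 (adjusted p = 0.095, range 0.00075 to 0.29). The immediate early list had a camera adjusted p of 0.053 (median −0.66), and 0.0079 without library 3 labelled Zfp292-OE (range over 19 alternatives 0.0063 to 0.50). Of 12 genes of the unfolded protein response, 1 rose, 2 fell and 9 did not pass, with 1 and 3 when adjusted over the list alone, and the camera adjusted p was 0.29 (median −0.24). Sdf2l1 rose by 0.95 and Hyou1 fell by 2.21, both factors of protein folding in the endoplasmic reticulum.

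Ribosomal protein genes differed by less. Of 17 tested, 5 rose, 0 fell and 12 did not pass, with 6 higher when adjusted over the list alone, and the median was 0.34. Rpl4 rose from 68303 ± 1968 (SD, n = 2) to 107638 ± 1786 (SD, n = 3), with no call after quantile normalization (adjusted p = 0.073, range over 17 alternatives 3.2e-07 to 0.20), and Rpl13 (0.55), Rpl7 (0.48) and Rplp0 (0.43) passed narrowly and lost their calls in each fit that left out a library. These genes have many processed copies in the genome, so their counts are uncertain. The list passed in camera (adjusted p = 0.0019), but not with an estimated correlation (adjusted p = 0.50), after quantile normalization (0.17) or without control library 1 (0.059, median 0.19), with a range of 1.1e-06 to 0.50 over 19 alternatives.

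Of 26 lists tested with camera, 14 passed with the preset correlation, 7 higher and 7 lower, and 0 with an estimated correlation, where 2 had an unadjusted p below 0.05. With 5 libraries the latter test has little power, whatever the correlation. For bipolar genes the estimate was −0.071, under the preset 0.01, yet the unadjusted camera p was 1.9e-08 with the preset and 0.0094 with the estimate. Every other list that passed with the preset had an estimate above it, from 0.062 for rod genes to 0.87 for G2/M genes. For those lists the p-values with the preset may be too small. A call missed with an estimated correlation does not by itself show whether correlated genes made the preset call. By fry, which asks whether the genes of a list move one way on balance, 5 passed: G1/S, G2/M, rod, bipolar and vascular. Setting members with 3 reads or fewer in a group to the bound those reads allow left the median of each list as given.

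The 10 genes with the largest rise included 5 guanylate-binding or T-cell-specific GTPases, Gbp4, Gbp8, Gbp11, Tgtp1 and Tgtp2, which interferon induces. Gbp4 had 2 reads over the controls and 4586 over the libraries labelled Zfp292-OE, a ratio of 1755 (95% interval 485 to 14492). Gbp8 had 0 control reads and was at least 214-fold higher against a floor of 3 reads over the group. These families contain near-identical copies, so the split of reads among them is uncertain, and Gbp4, for example, had normalised counts of 1496, 86 and 3332 in libraries 1, 2 and 3. The calls for Tgtp1, Tgtp2, Gbp11 and Gbp8 were lost without library 1 (adjusted p = 0.12, 0.14, 0.084 and 0.055), with highest values over the alternatives of 0.34, 0.67, 0.40 and 0.33 and lowest of 4.4e-06, 0.00017, 3.9e-05 and 4.6e-08. Cardiac troponin T, Tnnt2, rose by 7.02 on the log2 scale (SE 0.66) at similar levels in the 3 libraries, 640, 771 and 746. Gpr142, a receptor for aromatic amino acids, had 0 control reads and was at least 89.5-fold higher. Cfap95, a protein of cilia, rose by 5.09 (6.04 without control library 1, 4.15 without control library 2), with normalised counts of 117 and 31 in the controls and 3236, 677 and 4141 in libraries 1, 2 and 3. The embryonic myosin Myh3 and the relaxin family receptor Rxfp2 were also among the 10, and edgeR did not call them (adjusted p = 0.050 and 0.13, ranges over 17 alternatives 0.00027 to 0.31 and 0.0071 to 0.36).

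Among the 10 genes with the largest fall, Bhlhe23, Grm6 and the bipolar homeobox gene Vsx1 (−7.27) belong to the bipolar list. The neuropeptide neurotensin, Nts, had 4654 reads over the controls and 3 over the libraries labelled Zfp292-OE, a ratio of 2027 (95% interval 693 to 9835). Its normalised counts differed between control libraries 1 and 2, at 3532 and 1088. Otor, a secreted protein first found in the cochlea, and Gsg1, a germ cell gene, also fell (−8.87 and −7.56). Without library 2 the values of Vsx1 and Gsg1 were −5.81 and −8.49, and they were −8.51 for Vsx1 without library 3 and −6.33 for Gsg1 without library 1. Higd1b, Mgp and the endothelin receptor Ednra had 0 reads in the libraries labelled Zfp292-OE and were at least 370-fold, 164-fold and 151-fold lower, and with Rgs5 these complete the 10. The log2 fold change of Ednra was −7.20, with −6.34 without control library 1 and −8.05 without control library 2. Mgp (adjusted p = 0.016) and Ednra (0.021) lost their calls with a filter at a mean of 50 (0.12 and 0.14), and Ednra with a replicate block (0.051), with ranges over 17 alternatives of 8.7e-08 to 0.12 and 4.0e-07 to 0.14. Higd1b, Ednra and Rgs5 are genes of pericytes. Intervals and floors cover counting error only.

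**Figure D3:**
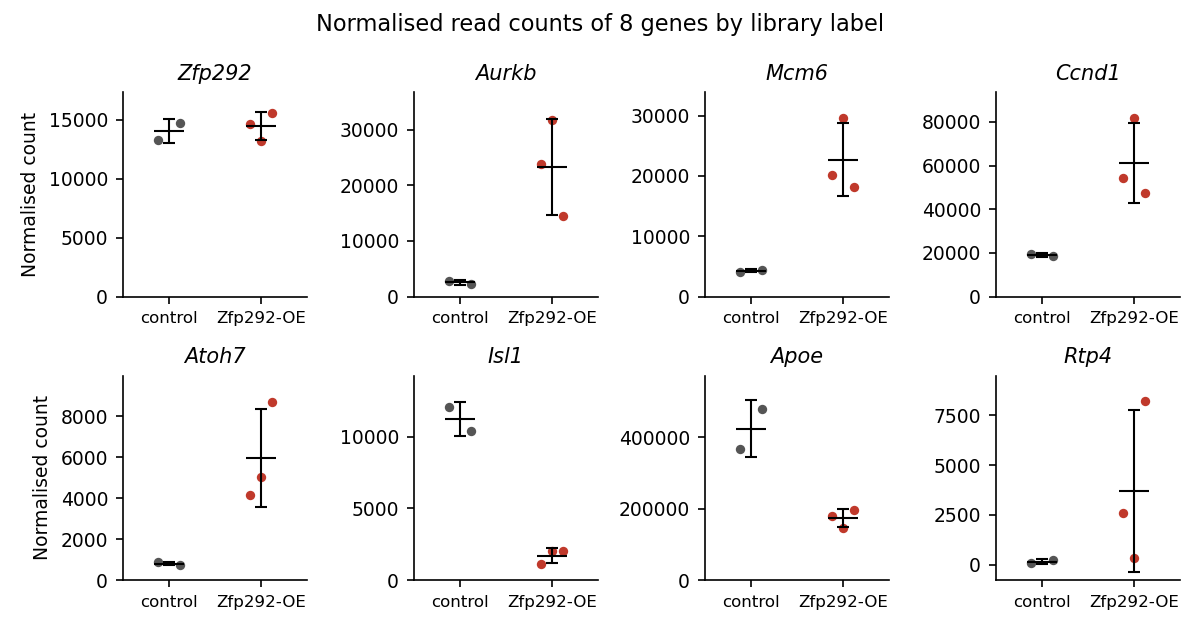
Normalised read counts of 8 genes in the 2 control libraries (grey) and the 3 libraries labelled Zfp292-OE (red), with points as libraries, horizontal lines as means and bars as 1 SD. Zfp292 overlaps between the groups, whereas Aurkb, Mcm6, Ccnd1 and Atoh7 are higher and Isl1 and Apoe lower in every labelled library, and Rtp4 is highest in libraries 1 and 3.

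The libraries grouped by label. Over the tested genes, the mean correlation of a library with its own group was 0.929 to 0.936, and with the other group 0.905 to 0.909, across genes, which are not independent replicates. The first principal component held 40.8% of the variance and separated the groups, and the second held 23.4% and set library 2 labelled Zfp292-OE apart from libraries 1 and 3. Library 2 also had almost no Y-linked reads: the normalised counts of Ddx3y were 6264 and 4282 in the controls and 6284, 7.52 and 14332 in libraries 1, 2 and 3. Xist, expressed from the inactive X chromosome, had counts of 10691 and 12123 in the controls and 5216, 7860 and 1407 in the others. The sexes of the pups are not given in the labels. No pair of libraries agreed within sampling noise, with chi-square per degree of freedom at 136 or more for every pair.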

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

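Only 1 alternative, leaving out libraries 1 and 3 labelled Zfp292-OE together, was chosen after the data were seen. None of the 2836 changed genes took the opposite sign under any of the 17 alternatives in which genes were refitted, but the number called varied. As the groups did not overlap for any of these genes, most alternatives could not reverse a sign. This holds for leaving out libraries, pseudocounts, filters and array weights. Leaving out 1 library at a time gave 1 to 2352 changed genes, 0 to 1359 higher and 1 to 993 lower, against 2836, 1632 and 1204. The low end came from leaving out either control, where the lone control is assumed to vary like the other group, and 81 named genes then lost their calls. Leaving out libraries 1 and 3 together gave 0 changed genes, 0 higher and 0 lower by limma, with 3330 genes at an unadjusted p below 0.05. In both cases fewer samples were tested. Equal totals gave 913 higher and 1986 lower genes, because that scaling shifts all values, and DESeq2 called 1838 lower genes and 4167 in all, with 319 adjusted p-values not given; the cause was not tested.

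The number of lists past the threshold was 14, and 8 (without control library 1) to 15 when 1 library was left out. It was 0 in camera with an estimated correlation and 5 by fry, which ask different questions of the same values. The direction of the test for p53 targets reversed with a mean of at least 50 (median −0.20) and with libraries 1 and 3 both left out (0.063). That for ganglion cells, which had no clear direction, turned after quantile normalization (0.24). It also turned with equal totals, where the median kept its sign (−0.30) and which says nothing about the list, as that scaling shifts all genes alike. Medians with 1 library left out ran from −0.27 to 0.45. Without control library 2 the late progenitor list, Tyrp1 and Hba-a1 reversed, and leaving out 1 library gave −0.22 to 0.070, −0.062 to 3.04 and −0.020 to 1.97. None of these had passed the threshold in the main fit, though Hba-a1 passed in limma with a replicate block (adjusted p = 0.038). The cause of the reversals was not tested.

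The log2 fold change of Zfp292 was −0.21 after quantile normalization, −0.17 with equal totals, −0.011 with a replicate block, −0.033 to 0.12 with 1 library left out and −0.086 with libraries 1 and 3 both left out. Over 17 alternatives it ranged from −0.21 to 0.12, with adjusted p from 0.39 to 0.98. As library differences, the mean correlation within groups exceeded that between groups by 0.0254, by 0.0121 with no filter and by 0.0382 with a mean of at least 50; the cause was not tested. Libraries share replicate numbers 1 and 2, but the labels do not say that these pair samples, so the main fit used no pairing. The deviations of same-numbered libraries correlated at −0.039 and −0.027. Both values rest on the same difference between the 2 controls and are not independent. A replicate block gave 2498 changed genes. Depth was similar in all libraries. In the simulated data, where only 200 genes were changed, limma recovered 4.48% of changes of 1.5-fold and 28.4% of those of 2-fold. The shares in the real data may differ.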

Other observations

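The gene groups in the first paragraphs here, and all tests but the one on GC content and transcript length, were chosen after the data were seen. The groups were put together from genes already seen to change, so no test of a group is given. That choice also raises the counts adjusted over a group alone, which are descriptive only, also for the immune GTPase genes below. Of 19 genes of cholesterol synthesis and uptake, 7 rose, 0 fell and 12 did not pass in limma (5 rose and 0 fell in edgeR), with 7 when adjusted over the list alone. Idi1, an isomerase of the pathway, rose from 11146 ± 3146 (SD, n = 2) to 47046 ± 6844 (SD, n = 3), and Msmo1 rose by 1.28, Fdft1 by 1.17 and Sqle by 0.85. Of 61 canonical histone genes, 9 rose and 0 fell in limma and in edgeR, 9 when adjusted over the list alone. For comparison, limma called 1632 of all 16316 tested genes higher. Their mean relative to control was 1.22 and 1.39 in libraries 1 and 2 and 0.14 in library 3. Near-identical copies make single histone genes uncertain.

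Of 24 imprinted genes, 3 rose, 5 fell and 16 did not pass, with 3 and 8 when adjusted over the list alone. Those that fell included the long noncoding RNA Meg3 (−1.63), the growth factor Igf2 (−1.94) and the growth regulator Dlk1 (−2.23), while the zinc finger gene Plagl1 rose by 1.04. Of 13 pericyte genes, 0 rose, 7 fell and 6 did not pass in limma (0 and 7 in edgeR), 8 when adjusted over the list alone, and the 7 include Rgs5, Higd1b and Ednra, from which the group was chosen. Rgs5, Kcnj8 (−6.78) and Acta2 (−5.87) are also the 3 vascular genes that fell, so the falls in these lists overlap. Normalised counts in control libraries 1 and 2 were 592 and 44 for Kcnj8 and 415 and 44 for Acta2.

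The main pattern is a rise of cell cycle genes with a fall of rod genes. A factor per library moves both alike, so only a scaling that depends on the level of a gene could part them, and quantile normalization, which is of that kind, left a gap of 4.57 log2 units between the G2/M and rod medians. GC content and transcript length are argued against as the whole cause, since the gap was 4.60 before and 4.22 after their trend was removed. A lower share of rods alone would raise other cell types alike. Yet the G2/M mean lay at least 1.83 above that of amacrine, horizontal and ganglion genes in each labelled library. The controls differed by 0.20. These values speak only to a change in rods alone. A change in the shares of several cell types at once, dividing cells among them, was not tested and remains open. Younger tissue in the labelled libraries remains open, as early progenitor genes lay 0.059 to 0.41 above late ones and the controls differed by 0.41. A later exit from the cell cycle in cells labelled as given the Zfp292 plasmid is a hypothesis that was not tested. This comparison would not tell such an exit from younger tissue.

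Zfp292 stood at a similar level in both groups although the labels name it as overexpressed. A control exchanged for an overexpression library is argued against, since each library correlated better with its own group, by at least 0.0206. Too little depth to see a doubling is argued against by the upper limit of 1.29-fold. Transcripts of the plasmid that were not counted under the gene, for instance from an insert of another species or with altered codons, could account for it, and this cannot be told apart from a plasmid that raised Zfp292 little, because the table has 0 rows for GFP or a plasmid. Loss of Zfp292 expression from the plasmid by the time of harvest was not tested.

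Immune GTPase genes were highest in libraries 1 and 3 labelled Zfp292-OE, and the group was chosen because 5 of them are among the 10 largest rises. Of 17 tested, 9 rose and 0 fell in limma (12 and 0 in edgeR), 11 when adjusted over the list alone, and their median over libraries 1 and 3 lay 4.52 above control, against 0.78 in library 2. A larger share of microglia in the sort is argued against, since the mean of microglial genes was lower in libraries 1 and 3 than in both controls, by −0.58 for the closest pair, while the controls differed by 1.63. The share of male pups stays open: library 1 had a Y-linked level 0.29 above control and a GTPase median 3.99 above it, but no second library of that kind is at hand. A response to the DNA or its delivery may also differ between electroporations, which the labels do not give, and an effect of the plasmid insert was not tested.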
